A study of Mus musculus with 37 samples.

How the data were processed

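Bone marrow cells of mice were grown into dendritic cells and treated with LPS or mock, with or without a ribosome inhibitor, and ribosome-protected fragments were sequenced, per the labels' protocols. Cycloheximide was used at 100 ug/mL for 1 min, harringtonine at 1 ug/mL for 5 min and lactimidomycin at 50 ug/mL for 30 min, per the labels. The 37 libraries were placed in 28 groups of inhibitor, stimulation and time from their labels. Only the cycloheximide LPS and naive groups have more than 1 library.

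Bowtie2, TopHat and the mm9 build are named in the submitters' processing notes, with no version or role. The ORF caller, its settings and its transcript models are not given in the sources used here. The deposited list has 1 line per ORF, with a transcript's exon blocks, the span of the ORF and a score. The score was assigned by the authors, is a whole number from 500 to 991 in these lines and is used here only to describe, rank or filter ORFs within this list. No line scores under 500, so ORFs with lower scores, if any were made, are not analysed here. It is assumed here that an ORF is listed only if its transcript is in the authors' models and holds enough footprints. Presence, number and score can then move with expression and depth, which the list does not give. The labels name this list for all libraries, so values per library, translation efficiency and changes with LPS were not analysed here, and the precision of a share is given as an exact Clopper-Pearson interval at the 95% level over ORFs or genes, which covers counting error only.

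The length in the name of all 22367 ORFs matched their coding bases, the stop codon included. Family names were matched to the symbols of a RefSeq gene table of another assembly, GRCm38.p6, which was used for names and gene types and for no coordinates. Of 10418 families, 9446 matched a symbol, 127 did so after a numeric suffix was dropped, 659 matched an older name and 186 did not match, of which 151 were assembled transcripts with no gene name. Some families carry the name of a hosted small RNA or appear to join neighbouring genes, which was not checked against gene coordinates. The classes of a gene's ORFs then follow the longest ORF of the family. Families were split by chromosome and strand. In each, the longest ORF was the main ORF (ties by score, then name). Other ORFs were classed by their position and frame against it: same stop with another in-frame start, isoform (shared in-frame codons otherwise), upstream, over the main start, within the main span, over the main stop, or downstream. The class of other in-frame starts was first computed with splice variants that have both the start and the stop of the main ORF. This was corrected to match the definition set before the data were examined, but after the list tests had been seen, and the correction changed which lists passed. The first version is given as an alternative.

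Median log2 length and median score were compared between each class and the main ORFs by two-sided permutation tests with 100000 resamples. The length tests, and that of ORFs over the main start against other upstream ORFs, are not reported as tests, because the definitions of the classes fix most of their outcome. Gene lists were compared with other genes by two-sided Fisher's exact tests: genes with a main ORF for upstream ORFs and in-frame starts, and all protein-coding genes of the naming table for presence. Each family of tests was adjusted by Benjamini-Hochberg at 0.05. The 20 gene lists, with 622 entries of which 616 matched a symbol, the classes, the tests and the other settings were set before the data were examined. Genes were named by a rule set then: for each class, the 5 families with the most ORFs and the 5 ORFs with the highest score; for each list, up to 6 members with an upstream ORF or another in-frame start, those with more ORFs first, and up to 3 members with no ORF; and 16 genes in any case. The text names a part of these. Values of some single genes are not reported here. Rules for start codons were planned and could not be run, since no genome sequence was used here. Alternatives were stricter scores, minimum lengths, 1 ORF per stop codon, the highest-scoring ORF as the main ORF, genes with high main scores, upstream ORFs that end before the main start, removal of the 3 mitochondrial ORFs, and 4 kinds chosen after seeing the data, the last with only 1 family per gene, that with the longest main ORF. After each filter on score or length, main ORFs and classes were assigned again among the ORFs left.

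The classes and tests were tested on simulated data. All 4000 simulated ORFs in 500 families were put in their true class. Each simulated family had a single transcript model, and its true main ORF was always the longest. Joined neighbouring genes, transcripts without the main start and a coding sequence that is not the longest ORF were not simulated. The result thus checks the class rules and not how well they hold in the deposited list. The permutation test gave a p under 0.05 in 3 of 100 runs with no shift and in 100 of 100 with a log2 shift of 0.5 in length. Fisher's exact test did so in 14 of 200 simulated lists with no change and in 184 of 200 with a raised share. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.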

Results

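The data were ribosome footprints, the short RNA fragments that translating ribosomes shield from nuclease, from mouse bone marrow-derived dendritic cells, antigen-presenting cells grown from marrow. The 37 libraries covered a time course of lipopolysaccharide (LPS), a bacterial cell wall component that activates these cells through Toll-like receptors, at 100 ng/mL and 8 time points from 0.5 to 12 h. Cycloheximide, which arrests elongating ribosomes, was used in 16 LPS libraries, 8 mock-treated libraries and 2 naive libraries. No inhibitor was used in 8 LPS libraries and 1 naive library. Harringtonine and lactimidomycin, which hold ribosomes near start codons, were used in 1 library each, both of mixed LPS time points. The values analysed here were a single list of 22367 open reading frames (ORFs), the stretches from a start codon to an in-frame stop codon that the authors scored as translated, made for all libraries together. It carried no value per library, so LPS, mock and inhibitor groups were not compared, the depth per library is unknown, and no ORF or gene had a replicate. The question addressed is which kinds of ORF were called in these cells and in which genes. Each test below compares ORFs or genes inside this list, which are not replicates of an experiment, so its p-value does not measure variation between cultures.

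Besides the longest ORF of each family of transcripts, the dendritic cells' list held many short ORFs upstream of it. The ORFs fell into 10418 families of transcripts, of which 10182 genes could be named, and 10071 of those were protein coding. The longest ORF of each family, called the main ORF, had a median of 435 codons. Upstream ORFs, which ended before the main start, numbered 2857 (12.8%) with a median of 16 codons. Upstream ORFs with different starts and a common stop codon were counted separately, here and in the counts per gene below. Another 692 ORFs (3.09%) began upstream and ended past the main start in genome position, sharing no in-frame codon with the main ORF, with a median of 37.5 codons. These are called over the main start here. Of them, 650 lay on a listed transcript that holds the main start, and the rest span it in the genome only. A further 3406 ORFs (15.2%) ended at the main stop codon but used another in-frame start, and 3335 (14.9%) were in-frame isoforms that shared codons with the main ORF. The span of the main ORF held 1250 ORFs (5.59%) in another frame or exon, 35 ORFs ran over the main stop, and 374 lay downstream of it. Named by the number of ORFs of their class were the upstream-rich families of Fes, a tyrosine kinase, Homer1 and Nlrc5, a regulator of MHC class I genes, with 11 upstream ORFs each. Pira1, a paired immunoglobulin-like receptor, had 12, but all lay on listed transcripts without its main start, and 6 of them had 474 to 680 codons. The 1932-codon main ORF of Nlrc5 had a score of 767, and its upstream ORFs had 9 to 52 codons. Of the 11 in Fes, 4 had 667 to 803 codons, and 5 lay on transcripts without its main start, as did 2 of the 11 in Homer1. The rest in Fes stopped 2879 to 5309 transcript bases before that start, while the listed transcript of the main ORF itself had a leader of 119 bases. Whether the upstream ORFs of this family belong to Fes or to a neighbouring gene was not tested.

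**Figure D1:**
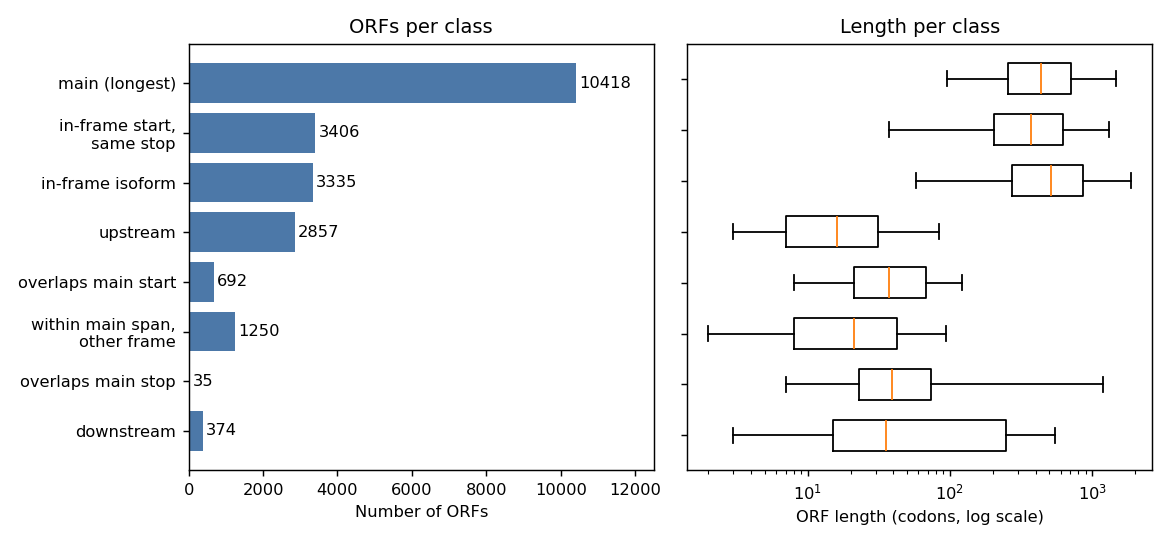
The left panel plots the number of ORFs in each class, and the right panel plots ORF length in codons on a log axis, with the median as a line, the quartiles as a box and whiskers at the 5th and 95th percentiles. The 2857 upstream ORFs had a median of 16 codons against 435 for the 10418 main ORFs.

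The main ORF is the longest of its family by definition, so lengths are described without a test. The difference of median log2 length from the main ORFs was -4.76 for upstream ORFs, -3.54 for those over the main start, -4.37 for those within the main span, -3.48 for those over the main stop, -3.62 for downstream ORFs, -0.23 for other in-frame starts and 0.24 for in-frame isoforms. The authors' score, which ran from 500 to 991, had a median of 926 for main ORFs, 916 for isoforms, 776 for upstream ORFs and 669 for other in-frame starts. The median score was lower than that of all main ORFs in all 7 classes, with an adjusted p of 0.0204 for isoforms and of at most 4.7e-05 for the rest by two-sided permutation tests. These tests pooled all families and did not pair an ORF with its own main ORF. Of the other in-frame starts, 1453 of 3406 scored above their own main ORF. ORFs from a common start often had the same score, so ORFs were not independent, and the p-values overstate the evidence.

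Upstream ORFs were found in 2027 of the 10182 genes (19.9%, 95% Clopper-Pearson interval 19.1 to 20.7), counting those over the main start. Kinases of the MAPK and PI3K pathways, which relay signals from surface receptors, had them in 17 of 37 genes (45.9%, interval 29.5 to 63.1), against 19.8% of other genes (adjusted p = 0.00277, Fisher's exact test, two-sided, over 19 lists). Akt2, a kinase downstream of PI3K, had 7 upstream ORFs, with starts that share a stop codon counted separately. Of these, 5 had 6 to 17 codons and lay at chromosome 7, 28376789 to 28393705, in the leader of a 481-codon main ORF that began at 28393727 and scored 985, and the others had 413 and 387 codons and stopped 11127 transcript bases before that start. Map3k3 had 4, among them a 6-codon ORF with a score of 966 at chromosome 11, 105946016 to 105946036. Syk, the kinase of immunoreceptor signalling, had 3 upstream ORFs and 2 classed as over its main start by genome position, and Jak2, a cytokine receptor kinase, had 3 upstream ORFs. All coordinates are mm9, counted from 1.

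Ribosomal protein, proteasome and oxidative phosphorylation genes had upstream ORFs less often than other genes. Cytosolic ribosomal proteins had an upstream ORF in 1 of 77 genes (1.30%, interval 0.0329 to 7.02) against 20.0% of other genes (adjusted p = 1.97e-05, Fisher's exact test). That gene was Rps12, with 3 upstream ORFs of 22 to 29 codons and 3 over its main start. Subunits of the proteasome, the complex that degrades tagged proteins, had none in 31 genes (interval 0 to 11.2%, adjusted p = 0.0108, Fisher's exact test). Nuclear-encoded genes of oxidative phosphorylation had an upstream ORF in 2 of 58 genes (3.45%, interval 0.420 to 11.9, adjusted p = 0.00277, Fisher's exact test). These were Ndufs1 and Cox8a, by the rule that the longest ORF of a family is the main ORF. In the Ndufs1 family, an upstream ORF of 727 codons scored 986 against 558 for the 1021-codon longest ORF. It stopped 29370 transcript bases before the start of that ORF. In the Cox8a family, a 69-codon upstream ORF scored 991 against 630 for the 271-codon longest ORF, and stopped 621 bases before it. Which of these ORFs encodes the named protein was not tested, so both genes may count through the rule alone. With a minimum of 30 codons, which left 8.5% of genes with an upstream ORF, none of the 4 lists passed, with differences of -7.24 points for ribosomal proteins, -8.53 for the proteasome, -5.08 for oxidative phosphorylation and 10.5 for kinases. With a score of 900 or more, which left 5.58%, none of the 4 passed either, with differences of -5.65, -5.61, -5.63 and 9.27 points in the same order.

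**Figure D2:**
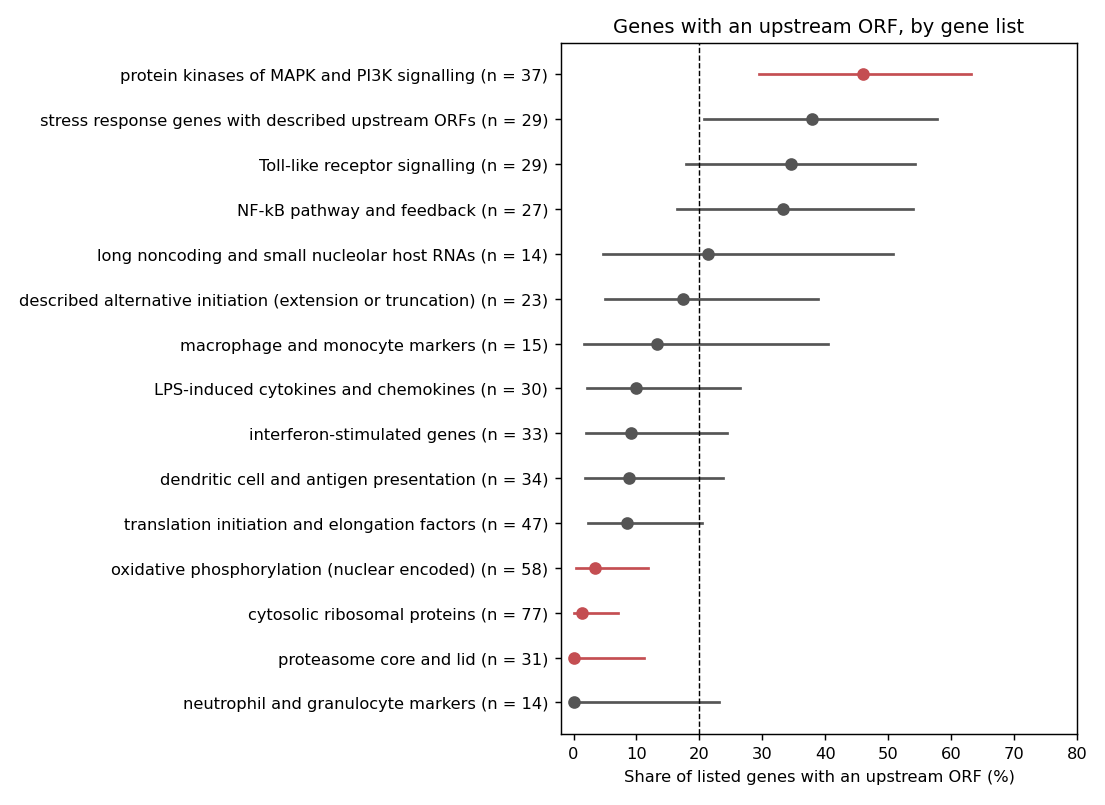
Points are the share of the genes of each fixed list, in percent, that had an upstream ORF or an ORF over the main start, with 95% Clopper-Pearson intervals as lines, for lists with at least 10 genes. Red marks the 4 lists with an adjusted p under 0.05 and the dashed line the share in other genes, and the kinases lie highest at 45.9%.

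Immune gene lists did not pass this test, though members carried upstream ORFs. Toll-like receptor signalling genes had them in 10 of 29 (adjusted p = 0.175), NF-kB pathway genes in 9 of 27 (0.192), cytokines and chemokines induced by LPS in 3 of 30 (0.396), interferon-stimulated genes in 3 of 33 (0.322) and dendritic cell and antigen presentation genes in 3 of 34 (0.25), all by Fisher's exact test. Of the 9 NF-kB genes, Nfkb2 counted only through a second family of that name, on the opposite strand, and with only the family of the longest main ORF for each gene, a count added after seeing the data, 8 of 27 had them (adjusted p = 0.387, Fisher's exact test). Tirap, an adaptor of Toll-like receptors, had 7, among them a 33-codon ORF with a score of 980 at chromosome 9, 34999180 to 34999281, and Tlr3, a sensor of double-stranded RNA, had 4. Cflar, an inhibitor of caspase activation, had 4, of which a 32-codon ORF scored 989 and stopped 2 bases before the main start. Socs1, a feedback inhibitor of cytokine signalling, had upstream ORFs of 10 and 34 codons that both stopped 1 base before the main start. Zc3h12a, an endonuclease that degrades cytokine mRNAs, and the chemokine Ccl5 each had an ORF over the main start with a score of 991, of 24 and 11 codons, that overlapped the main ORF by 4 bases. The NF-kB difference from other genes was 22.5 percentage points among ORFs with a score of 900 or more (adjusted p = 0.00574, Fisher's exact test), but -1.10 with a minimum of 30 codons and -1.30 with the highest-scoring ORF as the main ORF.

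Stress response genes with described upstream ORFs had them in 11 of 29 (37.9%, interval 20.7 to 57.7, adjusted p = 0.121, Fisher's exact test). The difference from other genes passed the test among ORFs with a score of 900 or more (17.6 points, adjusted p = 0.0232) and at or above the median score (18.3 points, adjusted p = 0.0178), and not with a minimum of 30 codons (9.38 points, adjusted p = 0.348), all by Fisher's exact test. Azin1, a regulator of polyamine synthesis, had 4, and Mief1, a mitochondrial fission factor, had 3, among them a 70-codon ORF with a score of 931. Atf4, the transcription factor of the integrated stress response, was listed with a single ORF of 59 codons (score 952) at chromosome 15, 80086111 to 80086811, with 1048 transcript bases after its stop. Ddit3, a transcription factor induced by endoplasmic reticulum stress, was listed with ORFs of 34 and 31 codons that share a stop, with 730 bases after it. Ppp1r15a, which directs dephosphorylation of initiation factor eIF2, was listed with a single ORF of 26 codons (score 953) and 2072 bases after it. Each of the 3 genes thus counted as having a short main ORF and no upstream ORF here, because the longest listed ORF is taken as the main ORF. Whether these short ORFs lie upstream of a longer coding sequence absent from the list was not tested for these genes. If they do, 11 of 29 is an undercount. The stress list passed the test when genes with such short main ORFs were left out, a setting chosen after seeing the data.

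**Figure D3:**
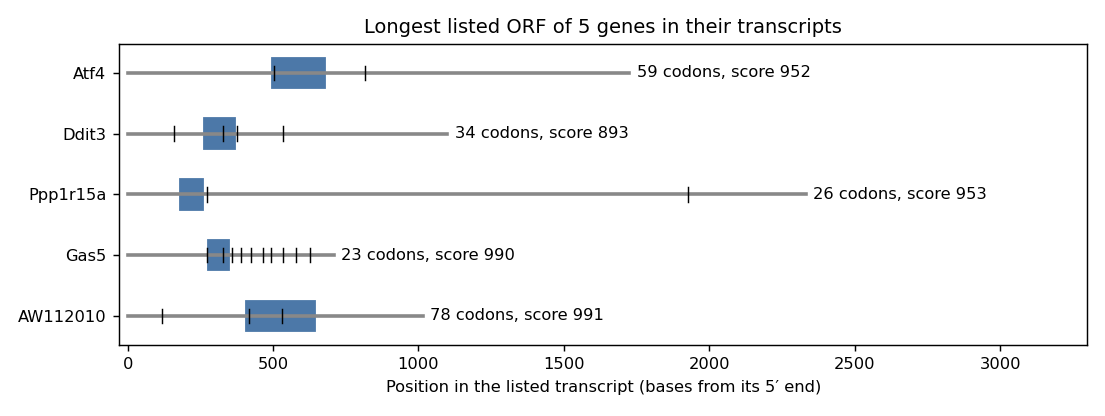
Each grey line is the listed transcript of a gene, drawn to scale in bases from its 5′ end, the blue box its longest ORF and black ticks its exon junctions. The ORFs of Atf4, Ddit3 and Ppp1r15a have 59, 34 and 26 codons with 1048, 730 and 2072 bases after the stop, and those of the RNAs Gas5 and AW112010 have 23 and 78 codons.

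In the other lists, upstream ORFs were found in 4 of 47 translation factors, 4 of 23 genes with described alternative initiation, 3 of 14 genes of the list of long noncoding and small nucleolar host RNAs, 2 of 15 macrophage and monocyte markers, none of 14 neutrophil markers, none of 7 fibroblast markers, none of 5 mast cell markers, none of 2 B cell markers and not in the single T cell marker present. None of these lists passed the test, with adjusted p-values from 0.175 to 1 by Fisher's exact test. In the noncoding RNA list, Mtln and 1810058I24Rik are protein coding in the naming table. The macrophage marker Msr1 counted through an ORF over its main start by genome position, on a listed transcript without that start. Eif4g2, a translation initiation factor, had 1 upstream ORF of 16 codons with a score of 931 and 5 ORFs within its main span. The highest scores among upstream ORFs, 991, included a 52-codon ORF of Ifrd1, a transcriptional regulator, that stopped 43 bases before the main start.

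Most upstream ORFs lay on a listed transcript with the main start. Of 2857, the listed transcript of 2674 (93.6%, interval 92.6 to 94.5) held the main start, and the median distance from their stop to it was 117 bases, with quartiles of 46 and 260. The median distance from the transcript start to the start of an upstream ORF was 246 bases. Where a listed transcript holds the main start, its own leader bounds these distances, and the placement within it was not tested. The leader had a median of 186 bases over all main ORFs. That value is of their own listed transcripts, which can differ from those of the upstream ORFs, so it is not this bound. ORFs over the main start made up 19.5% of both kinds together (interval 18.2 to 20.8) and had a median of 37.5 codons against 16. A longer ORF is more likely to reach the main start, so this split by itself favours longer ORFs over the start, and the length difference is given without a test.

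Other in-frame starts were listed in 2357 of 10182 genes (23.1%, interval 22.3 to 23.98). NF-kB pathway genes had them in 13 of 27 (48.1%, interval 28.7 to 68.1) against 23.1% of other genes (adjusted p = 0.0299, Fisher's exact test), among them Ikbke, an IkB kinase with 3, and Bcl3, an IkB family member with 2. Ribosomal proteins had them in 5 of 77 (6.49%, adjusted p = 0.00357) and proteasome subunits in 1 of 31, Psmc3 (3.23%, adjusted p = 0.0299), both by Fisher's exact test. Among genes with a main score at or above the median no list passed, with differences of 16.2 points for NF-kB genes, -7.62 for ribosomal proteins and -8.40 for the proteasome. Among ORFs with a score at or above the median of 847, with classes assigned again, 1.21% of genes had another in-frame start. No list passed either, with one in no NF-kB gene (-1.21 points) and 0.106 for ribosomal proteins. In-frame starts of Ikbke (score 944) and Bcl3 (871) were kept. Their main ORFs, at 826 and 613, were removed, so these starts became the main ORFs and no longer counted. With the highest-scoring ORF as the main ORF, the NF-kB (15.3 points) and proteasome (-18.6) lists no longer passed. Counting splice variants with the same start and stop as well, the NF-kB list no longer passed (adjusted p = 0.0917, Fisher's exact test) and the share of genes was 38.2%.

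Cebpb, a transcription factor with known protein isoforms, had 5 starts with a common stop, giving 296, 292, 275, 120 and 79 codons, with scores of 922, 548, 712, 547 and 578. Myc, a growth-promoting transcription factor, had ORFs of 453 and 435 codons with scores of 838 and 729. Tnf, the inflammatory cytokine, had a 268-codon ORF with a score of 677 and ORFs of 235 and 234 codons from a common start with a score of 955. In Hif1a, the hypoxia regulator, the 836-codon ORF scored 511 and 3 ORFs of 824, 817 and 810 codons from a common start scored 985. Pim1, a serine/threonine kinase, had 397 codons with a score of 667 and 313 codons with a score of 989. Over all families, 1940 of 3406 such ORFs (57.0%) scored below their main ORF and 1453 above it. Starts that were themselves a codon of the main ORF lay a median of 23 codons inside it, with quartiles of 10 and 64.

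Genes with described alternative initiation had other in-frame starts in 10 of 23 (adjusted p = 0.164, Fisher's exact test). The counts were 9 of 33 in interferon-stimulated genes, with 4 such ORFs from 3 starts in Stat2, 9 of 29 in Toll-like receptor signalling, with Myd88 at 3, 9 of 34 in dendritic cell genes, 9 of 29 in the stress list, 12 of 37 in kinases, 9 of 47 in translation factors, 7 of 58 in oxidative phosphorylation and 3 of 30 in cytokines. They were 4 of 14 in neutrophil, 4 of 15 in macrophage, 1 of 7 in fibroblast, none of 5 in mast cell, 1 of 2 in B cell and 1 of 1 in T cell markers, and 2 of 14 in the list of long noncoding and small nucleolar host RNAs. None of these passed the test, with adjusted p-values from 0.164 to 1 by Fisher's exact test. Mavs, an antiviral adaptor, Nfkbia, the inhibitor IkB-alpha, Il1b, Cd14 and Irf8 had a single ORF each, of 503, 314, 269, 366 and 424 codons. Il6 had a 211-codon ORF and a 4-codon ORF within its span, and Irf1 a 329-codon ORF and a 40-codon isoform from the same start.

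The list held most genes of the dendritic cell response and all neutrophil markers, and few T cell, NK cell or red cell markers. Of protein-coding genes outside a given list, about 46.0% had an ORF. All 27 NF-kB genes, all 29 Toll-like receptor genes and all 31 proteasome genes were present, as were 30 of 33 LPS-induced cytokines, 31 of 34 interferon-stimulated genes and 34 of 39 dendritic cell genes. Also present were 29 of 30 stress genes, 23 of 30 genes with described alternative initiation, 77 of 79 ribosomal proteins, 47 of 50 translation factors, 58 of 59 oxidative phosphorylation genes and 37 of 38 kinases. All 12 of these lists passed the test, with adjusted p-values from 1.6e-22 to 0.00106 by Fisher's exact test. None of 10 erythroid markers was present (adjusted p = 0.00314) and of 14 T and NK cell markers 1 was, the kinase Lck (adjusted p = 0.00314), both by Fisher's exact test. Markers of neutrophils were present in 14 of 14 (adjusted p = 2.98e-05) and of macrophages and monocytes in 15 of 16 (adjusted p = 0.000191), by Fisher's exact test. Those of mast cells (5 of 11), fibroblasts (7 of 12) and B cells (2 of 9) did not pass it, with adjusted p-values of 1, 0.426 and 0.215. Presence was counted by family name, so a gene whose ORFs are listed under the name of a neighbouring gene counts as absent. An absent gene is thus not shown to be untranslated. Presence is not a level, and with a score of 900 or more the neutrophil markers no longer passed (adjusted p = 0.159, Fisher's exact test).

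**Figure D4:**
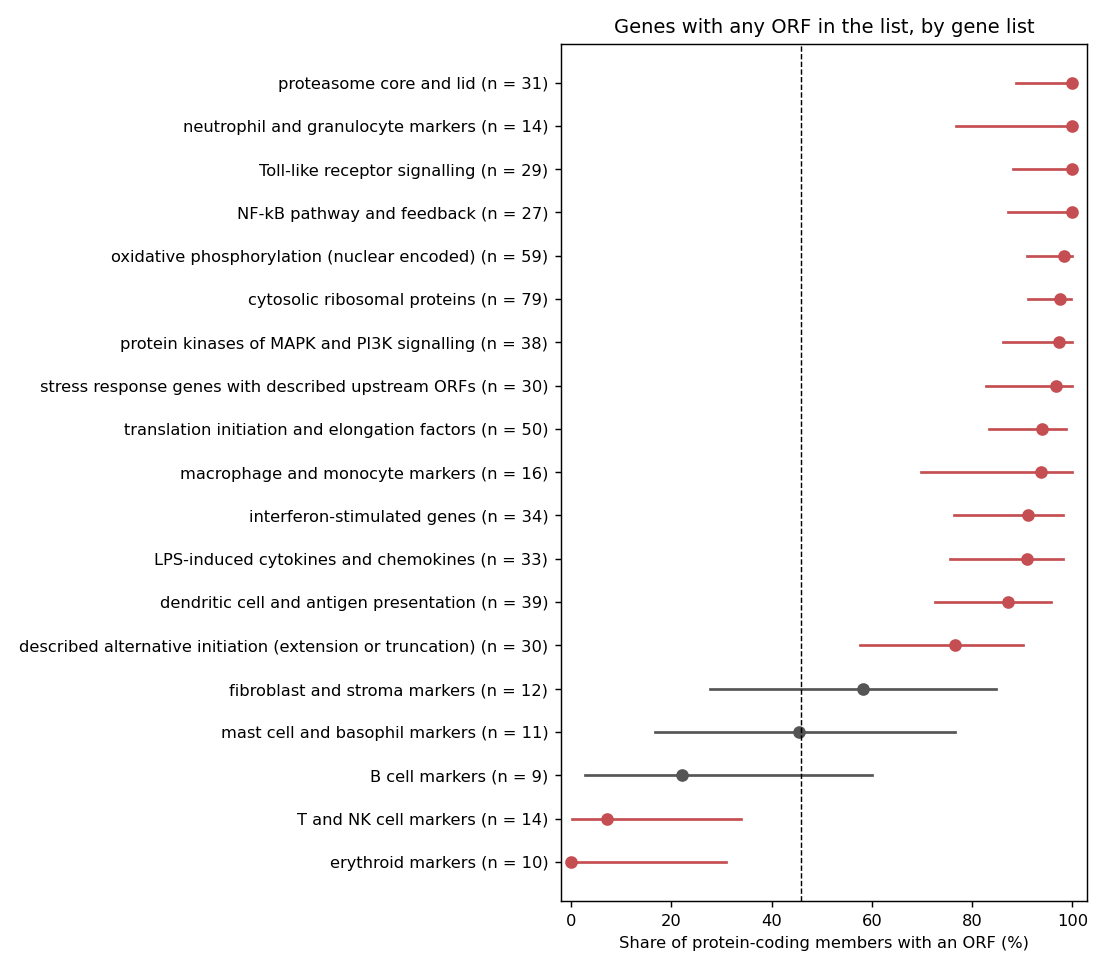
Points are the share of the protein-coding members of each fixed list, in percent, that had any ORF, with 95% Clopper-Pearson intervals as lines. Red marks lists with an adjusted p under 0.05 and the dashed line the share in other genes, with erythroid markers at 0 and neutrophil markers at 100.

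Of the 10182 genes, 5743 (56.4%, interval 55.4 to 57.4) had more than 1 ORF, 731 had 5 or more and 36 had 10 or more. Outside protein-coding genes, 74 genes of long noncoding RNAs had 196 ORFs, with a median of 52.5 codons for the longest of each. Gas5, a host of small nucleolar RNAs, had a 23-codon ORF with a score of 990 at chromosome 1, 162965885 to 162966134. AW112010, a transcript induced in activated immune cells, had a 78-codon ORF with a score of 991 at chromosome 19, 11122470 to 11124886. Tug1 had a 142-codon ORF with a score of 982, Neat1 a 79-codon ORF with a score of 839, and Morrbid, which regulates myeloid cell survival, had 8 ORFs, of which a 43-codon and a 20-codon ORF scored 974.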

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

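Of 758 recomputed values of 87 results, 629 kept their direction, their side of the threshold or their size, 57 moved, 24 lost and 8 gained a call, and 40 changed sign, 32 of these with no call on either side. The 100-codon settings, the count with splice variants and 1 family per gene were chosen after seeing the data. Length calls, among those counted, carry no weight, since the main ORF is the longest by definition. Score comparisons under a score filter carry none either, since the filter selects on the score itself. A list with no such member differs by minus the share in other genes, which shows no reversal. Differences below are in percentage points against other genes unless stated. The cause was not tested for any of them, except that a stricter score or minimum length leaves fewer ORFs by construction. Main ORFs and classes were assigned again among the ORFs left by each such filter. Where a main ORF was removed, an ORF that was kept could change class or become the main ORF. Depth per library is unknown and limits every count. No paired analysis was possible because the list has no column per library, which also rules out leaving out replicates. Start codons, the match of exon structures and removal of paralogs were not run, as no genome sequence was used here, and the overlap choice does not apply to in-frame starts or to geometry.

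With a score of 900 or more, ORFs fell to 9208: 6784 main, 33 other in-frame starts, 1799 isoforms, 392 upstream, 61 over the main start, 66 within the main span, 3 over the main stop and 70 downstream. Genes with an upstream ORF were 5.58%, with another in-frame start 0.434% and with more than 1 ORF 25.3%, and 13.5% of upstream ORFs overlapped the main start. Lists that differed were 2 for upstream ORFs and 0 for in-frame starts. Upstream calls were lost for ribosomal proteins (-5.65), proteasome (-5.61), oxidative phosphorylation (-5.63) and kinases (9.27), and gained for NF-kB (22.5) and stress genes (17.6). The sign turned for cytokines (1.57) and described alternative initiation (5.54), and no Toll-like receptor gene had one (-5.60). The latter holds only with classes assigned again after the filter, since an upstream ORF of Tirap in the full list passed it. The 33 in-frame starts left were too few to compare lists. With classes assigned again, these lists had no member with one: NF-kB (-0.436), ribosomal proteins (-0.439) and proteasome (-0.436), which all lost their call, and Toll-like receptor genes (-0.435), stress genes (-0.436), kinases (-0.436) and B cell (-0.434), neutrophil (-0.434) and macrophage markers (-0.435). Presence was no longer called for neutrophil markers (19.8) and turned for fibroblast markers (-21.9). Isoforms scored 2 above main ORFs, and the log2 length difference of other in-frame starts was -0.0316.

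With a score at or above the median, ORFs fell to 11199: 112 other in-frame starts, 2123 isoforms, 650 upstream, 113 over the main start, 130 within the span, 8 over the main stop and 94 downstream. Shares of genes were 7.73% with an upstream ORF, 1.21% with another in-frame start and 28.2% with more than 1 ORF, and 14.8% of upstream ORFs overlapped the start. Upstream calls were lost for oxidative phosphorylation (-7.78) and proteasome (-7.76), gained for NF-kB (20.3) and stress genes (18.3), and the sign turned for Toll-like receptor genes (-4.04) and described alternative initiation (2.28). For in-frame starts 0 lists differed. With classes assigned again, no member with one was left in NF-kB (-1.21) and the proteasome (-1.22), which both lost their call, nor in kinases (-1.22) and B cell (-1.21), macrophage (-1.21) and neutrophil markers (-1.21), the ribosomal call was lost with a turned sign (0.106), and the sign turned for cytokines (2.25), oxidative phosphorylation (0.547) and translation factors (1.07). In Ikbke and Bcl3 of the NF-kB list, an in-frame start was kept but had become the main ORF. Presence was no longer called for neutrophil markers (21.7) and turned for fibroblast markers (-2.16). Isoforms scored 3 above main ORFs, not called, and the length difference of other in-frame starts was -0.10.

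With at least 10 codons, 1901 upstream ORFs were left, 15.4% of genes had one, 53.4% had more than 1 ORF, 25.3% of upstream ORFs overlapped the start, and described alternative initiation turned (2.04). With at least 30 codons, 776 upstream ORFs, 433 over the main start, 490 within the span, 22 over the main stop and 210 downstream were left. Then 8.5% of genes had an upstream ORF, 48.5% more than 1 ORF, and 35.8% of upstream ORFs overlapped the start. No list differed in upstream ORFs (0 lists): ribosomal proteins (-7.24), proteasome (-8.53), oxidative phosphorylation (-5.08) and kinases (10.5) lost their call, and NF-kB (-1.10), dendritic cell genes (0.324) and described alternative initiation (0.196) turned. The in-frame call of the proteasome was lost (-19.4).

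With 1 ORF per stop codon, 769 isoforms and 0 other in-frame starts were left, 31.0% of genes had more than 1 ORF, and the isoform length difference turned to -1.09 (log2). With the highest-scoring ORF as main, 16.1% of genes had an upstream ORF and 21.8% another in-frame start, 28.0% of upstream ORFs overlapped the start, 1 list differed in in-frame starts, with NF-kB (15.3) and proteasome (-18.6) no longer called, and upstream differences turned for NF-kB (-1.30) and macrophage markers (3.90). Among genes with a main score at or above the median, 17.4% had an upstream ORF and 11.6% another in-frame start, and 0 lists differed in in-frame starts: NF-kB (16.2), ribosomal proteins (-7.62) and proteasome (-8.40) lost their call. The in-frame difference of the noncoding RNA list turned there (0.909), no B cell marker had another in-frame start (-11.6) and no gene of the noncoding RNA list an upstream ORF (-17.4).

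Upstream ORFs that end before the main start were in 16.04% of genes, and those under 100 codons on a transcript with the main start in 18.7%. Among genes with a main ORF of 100 codons or more, the upstream call of stress genes was gained (24.1). This setting removes Atf4, Atf5, Ddit3 and Ppp1r15a, which counted as having no upstream ORF with the longest listed ORF as main. The in-frame difference of the noncoding RNA list turned with this setting (26.5). Counting splice variants with the main start and stop as other in-frame starts, as was first done, gave 5849 such ORFs and 892 isoforms in 38.2% of genes, and 5 lists differed. Cytokines (-24.9), described alternative initiation (35.8) and oxidative phosphorylation (-22.8) gained a call, NF-kB (21.1) lost it, and macrophage (-4.88) and neutrophil markers (-9.65) turned. The log2 length difference turned to -1.06 for isoforms and 0.0900 for other in-frame starts. With 1 family per gene, no call or direction changed, and the upstream difference of NF-kB genes was 9.82.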

Other observations

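All tests in this part were set after the gene list results were known, and for the short main ORFs and the long upstream ORFs some of the values they rest on had also been seen. The overlap and shared-start counts, and the naming of Atf5, were chosen after seeing the data.

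In 650 ORFs over the main start whose transcript holds that start, the overlap with the main ORF had a median of 47 bases, with quartiles of 14 and 104. Of these, 77 (11.8%) overlapped by exactly 4 bases, 28 by 8 bases, 10 by 1 base and 5 by 7 bases. Zc3h12a and Ccl5 are among those with 4. Scores were tied to the start codon: at 2053 of 2749 start positions with more than 1 ORF (74.7%), every ORF had the same score. Of 3090 stop codons with more than 1 start, 37 had more than 1 start with a score of 900 or more. Among families with no gene name, the highest main scores were 986, for ORFs of 55 and 54 codons.

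Ribosomal protein, proteasome and oxidative phosphorylation genes had few upstream ORFs, 3 of 166 genes with a median leader of 102 bases, and MAPK and PI3K kinases had many, 17 of 37 with a median leader of 289 bases. In permutation tests against 10000 random sets of other genes matched on decile of leader length, the sets had a median of 26 genes with an upstream ORF for the first (95% of sets from 18 to 34, p = 0.00020, the smallest they can give) and 9 for the kinases (4 to 14, p = 0.0048). In the same permutation test, sets matched on decile of the main ORF's score had a median of 24 (16 to 33, p = 0.00020) and 7 (3 to 12, p = 0.00060). These values argue against main score by decile as the whole cause of either difference. For leader length they do so only as measured on the listed transcript of the main ORF. The upstream ORFs can lie on other transcripts: that of the main ORF of Nlrc5 had a leader of 0 bases, while the family had 11 upstream ORFs. Leader length of the transcripts that hold upstream ORFs was not matched. The sets were also chosen because their lists had passed in these data. Expression, leader sequence and the authors' calling rules may still account for them and were not tested, nor was a biological explanation.

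Some protein-coding genes, 343 of 10071, had no ORF of 100 codons or more, among them Atf4, Atf5, Ddit3 and Ppp1r15a of the stress list but also 9 ribosomal proteins and 7 chemokines. If such ORFs lay in the leader of a longer coding sequence absent from the list, more transcript should follow their stop. As a set they had less, by a difference of -328 bases in the median (794 against 1122, p = 0.00046, permutation test, two-sided). Their median score was 942, above the median of 927 in other main ORFs, which argues against low-scoring calls for the set as a whole only. The set mixes small proteins with other genes, so an unlisted longer coding sequence or a low-scoring call may still apply to single members. Those of the stress list, and the 46 genes whose longest ORF is under 30 codons, were not tested apart.

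Long upstream and downstream ORFs, of 100 codons or more, had a listed transcript without the main start in 133 of 255 (52.2%) against 5.11% of shorter ones, a difference of 47.0 points (p = 3.0e-83, Fisher's exact test). The test counted ORFs, of which several can come from the same family and transcripts, as in Fes, so this p-value overstates the evidence. The difference has the direction predicted if neighbouring genes were joined under a common family name. No biological explanation was tested for this or for the short main ORFs.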
